A study of Mus musculus with 16 samples.

How the data were processed

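RNA was measured in laser-captured GAD67-GFP-positive cells of 16 mouse embryos, about 100 cells from each of 10 cortical sections of 10 µm, and libraries were made from total RNA with a kit for small inputs, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene symbol, with 24539 genes and 1 column per sample, and 18733 of these genes had at least 1 count. Reads were aligned with STAR 2.5 and the genome build was mm10, per the submitters' processing notes. The counting tool, its annotation, its use of strand and any filters are not given in the sources used here. The table held none of the 15 mitochondrially encoded genes that had been listed, so that list was not analysed here.

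Each sample was placed in its group by the exposures in its label: vehicle or cypermethrin, with or without restraint stress, 4 embryos per group and 1 embryo per litter. Replicate numbers were given in accession order and pair no samples. A code in the library descriptions divided the samples into 7 and 9, and it was treated as a possible batch, as 1 of the alternatives. Gene positions were taken from GENCODE, whose release vM21 uses the same build, and 23879 symbols matched. All 71 genes named by the rule had a unique entry, and examples of positions are Gad2 on chromosome 2 from 22622205 to 22693874, Ccnd2 on chromosome 6 from 127125162 to 127152193, Cnr1 on chromosome 4 from 33924593 to 33948831, Nes on chromosome 3 from 87971078 to 87980451, Cpeb1 on chromosome 7 from 81347026 to 81455465 and Dnajc1 on chromosome 2 from 18195654 to 18392830, each annotated as protein coding. Another gene of the table lies at the same place for 18 of the 71, among them Gad1, Gad2, Dlx1, Ccnd2, Dnajc1, Tbp, Spata46, Fam118b, Chst15 and Snhg10, and their counts are uncertain because strand use is not stated.

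The counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the 4 groups and a count minimum of 10, which left 13224, libraries were scaled by TMM, dispersions were estimated robustly, and a quasi-likelihood model with 1 mean per group was fitted to all 16 libraries. The common dispersion was 0.344, a biological coefficient of variation of 0.586, with 12 residual and 15.1 prior degrees of freedom. The 6 comparisons were each exposure and both against vehicle without stress, the interaction, and each exposure averaged over the other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors were derived from the F statistic and the fold change. Levels are CPM over TMM-scaled library sizes. The median standard error of a log2 difference was 0.54 for single groups, 0.76 for the interaction and 0.38 for the averages, and 0.27, 0.38 and 0.19 in the 25% of genes with the highest levels.

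Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry. Of the 29 lists with at least 5 tested members, 22 held pathway genes (interneuron identity and migration, channels and receptors, hormone, toxic and cellular stress responses, metabolism, cell cycle and death, and inflammation) and 7 held markers of other cell types. With an estimated correlation or with fry 0 lists were called in any comparison. Over all fits, alternatives included, camera made 51 list calls with the preset correlation, and 0 of them were kept with an estimated one (smallest adjusted p = 0.249 among them). List medians are over differences of mean log2 CPM, while genes of a list were counted as higher or lower by edgeR's fitted values, so the 2 can differ in sign. List scores are means of log2 CPM centred over libraries, compared by exact permutation tests. The named genes are the called genes or, with fewer than 10 called, the 10 with the smallest unadjusted p, leaving out models known only by clone or locus numbers (0 to 2 per comparison), then the 4 leading members of a called list, and a fixed set of interneuron, channel and stress response genes, of which 15 were tested while Fos and Nqo1 had too few counts. Tests, lists and this rule were chosen before the data were examined. The 3 examples of the fixed set given per comparison have the smallest p, which was chosen afterwards.

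The fits were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes. Genes tested were 12962 with edgeR and limma voom, and with DESeq2 12951 for cypermethrin without stress and 12945 for cypermethrin averaged over stress. Genes were drawn independently of each other, with no library made to stand apart, so recovery in the real libraries can differ. For cypermethrin without stress edgeR called 8 of 100 genes changed 2-fold and 37 of 100 changed 4-fold (33 of 50 above the median level), with 3 false calls. For cypermethrin averaged over stress it called 26 of 100 and 59 of 100 (47 of 50), with 6 false calls. DESeq2 called 19 and 53, then 41 and 75, with 22 and 24 false calls, and limma voom called 6 and 35, then 24 and 58, with 3 false calls each.

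Alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE and upper-quartile scaling, no filter on low counts, a mean of at least 50 counts (8736 genes), the library code as a term, only the groups compared, each library left out in turn, and, chosen after the data were seen, fits within each library code, where the first code held 1 library of cypermethrin without stress, the second held 3, each other group held 2 in each code, and 3 residual degrees of freedom were left in the first. Counting intervals cover counting error only, since reads are not independent molecules.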

Results

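Cells picked as migrating GABAergic cells by a GFP reporter were sampled from the cortical plate of embryonic day 14.5 mouse brains. The dams had been exposed to an insecticide, to restraint stress, to both or to neither. CD1 dams received alpha-cypermethrin, a pyrethroid that acts on voltage-gated sodium channels, by gavage at 10 mg/kg on each of gestational days 11 to 14, or corn oil as vehicle. Dams of the stressed groups were restrained under bright light for 3 sessions of 45 min on days 12 and 13, and once more on day 14, where restraint ended 15 min and the last gavage was given 90 min before euthanasia. GAD67-GFP-positive cells were laser-captured at the leading edge of their migration, about 1000 cells per embryo, from 1 embryo per litter, each recorded as male. The 16 libraries formed 4 groups of 4, and each replicate was an embryo of a separate litter. Total counts per library ran from 2291283 to 4324129, with a median of 3695782. Group means were 3538039 ± 350700 for vehicle without stress, 3350844 ± 793500 for cypermethrin without stress, 3133122 ± 697900 for vehicle with stress and 4011514 ± 315800 for both exposures (SD, n = 4 each).

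Transcripts of cortical interneurons were present in every library. Gad2, which encodes a GABA-synthesising enzyme, had a mean of 271 ± 82.0 CPM (counts scaled by library size, SD, n = 16). Gad1, which encodes GAD67 and drives the GFP reporter that marked the captured cells, had 70.0 ± 29.7 CPM. The transcription factor genes Lhx6 and Sox6, which define interneurons of the medial ganglionic eminence, had 281 ± 54.9 and 188 ± 31.1 CPM, and the neuropeptide gene Sst had 198 ± 73.5 CPM. Erbb4, the neuregulin receptor used in tangential migration, had 491 ± 83.1 CPM, and Dcx, a microtubule-associated protein of migrating neurons, had 3916 ± 509 CPM. Of genes used as marks of the ganglionic eminences or of interneurons of caudal origin, some were near the floor, with 0.693 CPM for Nkx2-1, 1.11 for Prox1, 0.0616 for Htr3a and no count of Lhx8 in any library, and others were not, with 691 ± 156 CPM for Cnr1, 172 ± 80.1 for Meis2, 87.8 ± 38.5 for Nr2f2, 65.7 ± 24.8 for Nr2f1 and 8.38 ± 7.45 for Calb2.

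Transcripts of neighbouring cell types were present over a wide range of levels. The glutamatergic neuron genes Neurod6, Sox5, Tbr1 and Bcl11b had 1325 ± 317, 1270 ± 258, 911 ± 173 and 679 ± 87.8 CPM (SD, n = 16). Reln, a product of Cajal-Retzius cells that some interneurons also make, had 2263 ± 376 CPM, and Trp73, a Cajal-Retzius marker, had 54.3 ± 25.1 CPM. Nes and Vim, intermediate filament genes of radial glia, had 393 ± 115 and 246 ± 74.6 CPM, while the progenitor transcription factor genes Pax6, Eomes and Hes5 had 8.43, 1.71 and 0.143 CPM. Meningeal and pericyte genes were present as well, with 558 ± 137 CPM for Igf2, 466 ± 172 for Col3a1 and 124 ± 89.2 for Rgs5. The endothelial genes Cdh5 and Cldn5 had 79.6 and 35.7 CPM, and the macrophage gene Mrc1 had 68.3 CPM. Several of these levels lie above those of Gad1 and Gad2, so the captured material held RNA of other cell types as well. The comparisons below concern that material as a whole, and the cells behind a difference cannot be told.

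**Figure D1:**
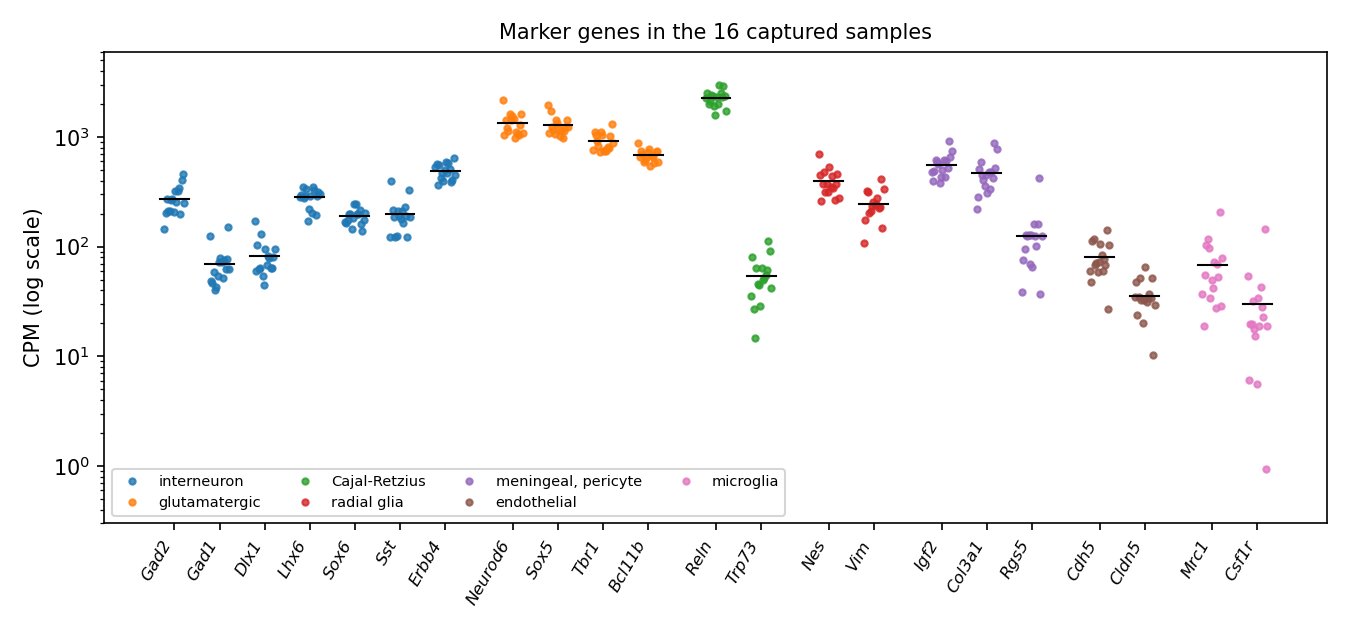
CPM on a log scale (vertical axis) of 22 marker genes, grouped by cell type (colours); each dot is 1 of the 16 libraries and each bar the mean. Interneuron genes such as Gad2 (271 CPM) lie below Neurod6 (1325 CPM) and Reln (2263 CPM).

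The sex-linked genes of 1 library went against its label. Xist, the RNA that coats the inactive X chromosome in female cells, had 9521 counts or 4528 CPM in the library labelled vehicle stressed replicate 1, against at most 26 counts or 8.14 CPM in the other 15. The same library had 1 count of Uty and no count of Ddx3y, Eif2s3y or Kdm5d, genes of the Y chromosome whose summed level in the other 15 libraries had a median of 301 CPM and was never below 198 CPM. The library was kept in its group.

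**Figure D2:**
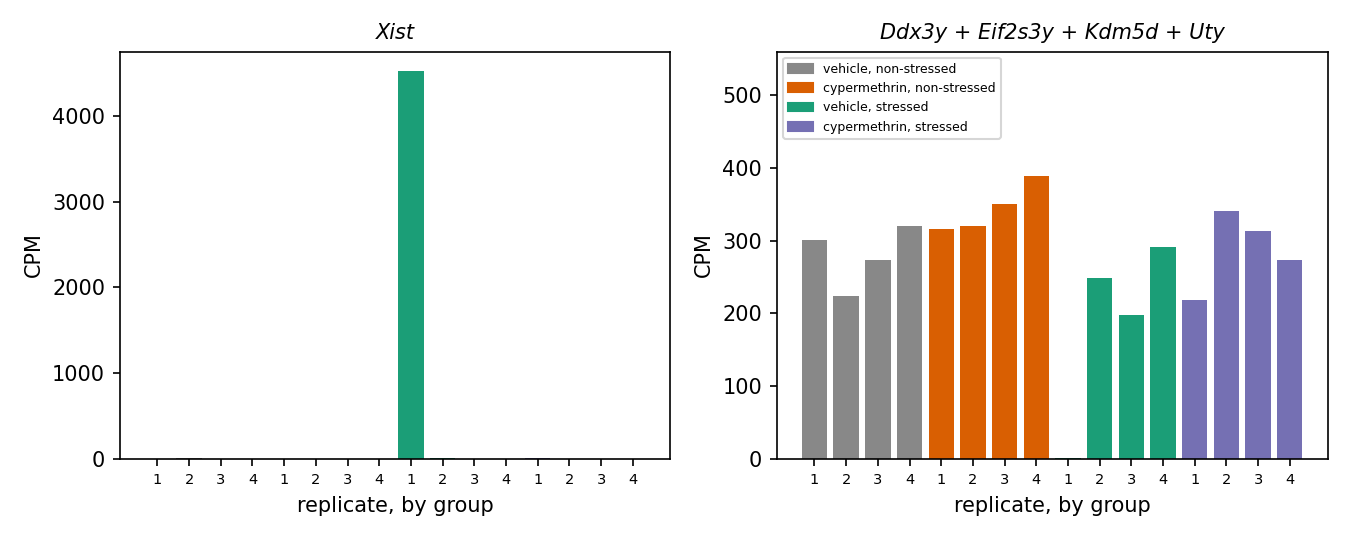
CPM of Xist (left) and of the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (right), 1 bar per library, coloured by group and ordered by replicate. The library labelled vehicle stressed replicate 1 has 4528 CPM of Xist and almost no Y-linked counts.

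Libraries of 1 group correlated with each other about as well as libraries of different groups. Over 13224 genes the median correlation of log2 CPM was 0.858 within groups (24 pairs) and 0.854 between groups (96 pairs), and no pair agreed within counting noise (lowest chi-square per gene 5.98). Group membership took up 19.8% of the squared distances between libraries, where 100000 permutations of the labels had a median of 19.9% (permutation p = 0.543). Cypermethrin took up 6.39% (permutation p = 0.691), stress 6.56% (permutation p = 0.479) and a code in the library descriptions, whose meaning is not stated, 7.30% (permutation p = 0.124). The first 4 principal components held 19.1%, 13.5%, 11.7% and 9.40% of the variance, and each was set by a single library: the one labelled vehicle stressed replicate 1, cypermethrin non-stressed replicates 3 and 4, and cypermethrin stressed replicate 1.

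Cypermethrin without stress was compared with vehicle without stress to ask what the insecticide alone did. No gene changed past the threshold. Among the genes with the smallest p were Ccnd2, a cyclin of the G1 phase, with a log2 difference of 0.58 ± 0.14 (SE, n = 4 per group) from 3480 ± 348 to 5197 ± 1325 CPM (SD), and Cnr1, the cannabinoid receptor, with 0.59 ± 0.15 from 596 ± 39.0 to 897 ± 182 CPM. Cpeb1, which controls polyadenylation and translation of stored mRNAs, had the largest difference of these, 4.45 ± 1.08, and it rested mainly on 35.1 and 75.7 CPM in replicates 3 and 4 of the exposed group, whose other libraries had 4.04 and 2.16 CPM. Mmrn1 (multimerin, 2.24 ± 0.58), Ints7 (an Integrator subunit, 2.05 ± 0.55), Ralb (a small GTPase, 2.35 ± 0.68), Palm2 (a paralemmin, 1.51 ± 0.43), Fam118b (1.39 ± 0.38), Bzw1 (0.86 ± 0.25) and Atxn10 (ataxin 10, 0.63 ± 0.18) completed the 10 genes with the smallest p, all higher with cypermethrin. Without cypermethrin non-stressed replicate 3 the differences of Mmrn1 and Ralb were 1.33 and 1.11, and without replicate 4 those of Ints7 and Cpeb1 were 0.73 and 3.38.

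Of the 15 interneuron, channel and stress response genes chosen beforehand and tested, 9 had higher and 6 lower fitted values with cypermethrin alone, with 0.55 ± 0.25 for Gad2, 0.72 ± 0.36 for Gad1 and -0.53 ± 0.33 for the interneuron transcription factor gene Dlx1. Gad1 also drives the reporter by which the cells were picked. Of the 11 tested sodium channel genes 5 were fitted higher and 6 lower, with a median of -0.08 over differences of mean log2 CPM, the values behind each list median given here. The 14 tested xenobiotic metabolism genes had a median of 0.30, with 9 fitted higher. By edgeR's quasi-likelihood test 0 of 13224 genes passed (smallest Benjamini-Hochberg adjusted p = 0.999), and 491 had an unadjusted p under 0.05 (315 higher, 176 lower). Uniform p values would give 661, while splits of the libraries of these groups, the real one included, gave 435 to 809. DESeq2 and limma voom also called 0, with 671 and 591 at an unadjusted p under 0.05. With the library code as a term edgeR called 0 as well. Fitted within each code, a choice made after the data were seen, it called 0 in the second code (498 at an unadjusted p under 0.05) and 2 in the first (90), Hbb-y and Cwc22. There 1 exposed library stood against 2 and had no spread of its own, and 35 of 100 splits of the libraries gave at least as many calls. Leaving out cypermethrin non-stressed replicate 1 raised the count at an unadjusted p under 0.05 over both codes from 491 to 809. Adjusted over the list alone, 2 genes passed, Cnr1 among genes of the caudal and lateral eminence (adjusted p = 0.00661) and Ccnd2 among cell cycle genes (0.00908), and 0 of the 15 chosen genes did. Such calls, here and in the other comparisons, are not adjusted over the 29 lists or the 6 comparisons, so some would pass by chance. None of the 29 gene lists was called by camera (smallest adjusted p = 0.462). Leaving out cypermethrin non-stressed replicate 3 or replicate 4 gave 2 calls each and leaving out vehicle non-stressed replicate 4 gave 1.

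**Figure D3:**
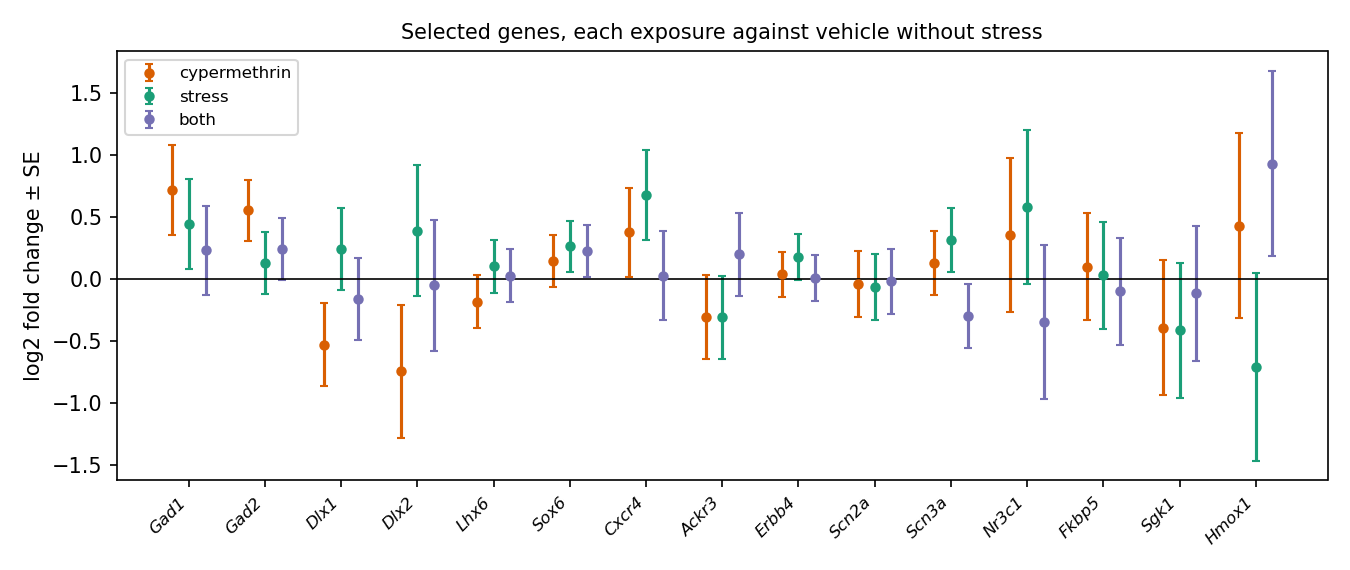
Log2 fold change (vertical axis) against vehicle without stress of the 15 chosen genes that were tested, for cypermethrin, stress and both exposures; dots are edgeR estimates and bars 1 SE. Gad2 (0.55 ± 0.25 with cypermethrin) and Hmox1 (0.93 ± 0.75 with both) are examples, and none of the 15 passed the test.

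Restraint stress without cypermethrin was compared with vehicle without stress to ask what stress alone did. No gene changed past the threshold. Nes, the progenitor intermediate filament gene nestin, had a log2 difference of 0.72 ± 0.20 (SE, n = 4 per group), from 327 ± 84.6 to 537 ± 116 CPM (SD). S1pr3, a sphingosine-1-phosphate receptor, had 2.40 ± 0.63, with 241.6 CPM in the library labelled vehicle stressed replicate 1 and at most 41.7 CPM in the rest of its group. Plekha8 (a glycolipid transfer protein, 1.54 ± 0.41), Snx1 (a sorting nexin, 1.92 ± 0.53), Inf2 (a formin, 2.22 ± 0.61), Zscan25 (3.95 ± 1.10), Ap5m1 (an adaptor protein subunit, 1.85 ± 0.52), Morc4 (3.19 ± 0.90) and Trim3 (a ubiquitin ligase, 1.48 ± 0.42) were also fitted higher with stress. Without the library labelled vehicle stressed replicate 1 the differences of S1pr3, Snx1, Morc4 and Trim3 were 0.79, 0.74, 1.68 and 0.79. That of Zscan25 was 5.34 without vehicle non-stressed replicate 3. The lone lower gene of the 10 with the smallest p was Fcer2a, a low-affinity IgE receptor, with 0.167 ± 0.194 CPM with stress and 6.63 ± 5.19 CPM without (SD, n = 4).

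Of the 15 chosen genes 11 were fitted higher and 4 lower with stress alone, with 0.68 ± 0.36 for the chemokine receptor gene Cxcr4, 0.26 ± 0.21 for Sox6 and 0.45 ± 0.36 for Gad1. The sign for Gad1 was opposite with limma voom (-0.12). Among 23 tested glucocorticoid response genes 13 were fitted higher and 10 lower, and among 21 immediate early genes 16 higher and 5 lower (median 0.08). Pericyte and meningeal fibroblast markers had a median of -0.56, with 13 of 17 fitted lower, and their mean score differed by -0.454 (exact permutation p = 0.371), or by -0.196 without the library labelled vehicle stressed replicate 1 (exact permutation p = 0.686). By edgeR 0 of 13224 genes passed (smallest adjusted p = 0.965) and 672 had an unadjusted p under 0.05 (423 higher, 249 lower), and DESeq2 and limma voom called 0 with 880 and 611 at an unadjusted p under 0.05. With the library code as a term edgeR called 0, and without the library labelled vehicle stressed replicate 1 it called 0 with 472 at an unadjusted p under 0.05. Within the library codes (2 against 2 libraries each) it called 45 genes in the first, of which 38 had their highest level in the library labelled vehicle stressed replicate 1 and without which it called 6, and 0 in the second (301 at an unadjusted p under 0.05). Without vehicle stressed replicate 4 the count at an unadjusted p under 0.05 over both codes was 1089, against 672. Adjusted over the list alone, 2 radial glia markers passed: Nes, which was higher (adjusted p = 0.0181), and Tnc, an extracellular matrix gene, which was lower by edgeR with -3.14 ± 1.03 (adjusted p = 0.0421) and at -4.61 without vehicle stressed replicate 3. None of the 29 lists was called by camera (smallest adjusted p = 0.333), but without vehicle non-stressed replicate 1 it called 1, the pericyte and meningeal fibroblast markers, which were fitted lower (adjusted p = 0.00175, and adjusted p = 0.974 with an estimated correlation).

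Both exposures together were compared with vehicle without stress to ask what the combined exposure did. No gene changed past the threshold. Blm, a DNA helicase, had a log2 difference of -2.24 ± 0.59 (SE, n = 4 per group), with 207.8 CPM in vehicle non-stressed replicate 2 and at most 31.7 CPM in the rest of that group. Dnajc1, a J-domain co-chaperone, had -1.21 ± 0.35, from 144 ± 33.8 to 62.5 ± 12.7 CPM (SD). Nop16, a nucleolar protein gene (-2.37 ± 0.75), Etv5, an ETS transcription factor gene (-2.36 ± 0.76), and the small nucleolar RNA host gene Snhg11 (-1.18 ± 0.40) were also fitted lower. Sez6l (0.76 ± 0.24), Mgat4b, a glycosyltransferase gene (1.54 ± 0.50), Ociad2 (1.85 ± 0.62) and Gdpd3 (3.89 ± 1.20, with 89.5 CPM in replicate 2 of the exposed group and at most 10.4 CPM in the rest of that group) were fitted higher. With 1 library left out Blm was at -0.77 (vehicle non-stressed replicate 2), Etv5 at -1.25 (vehicle non-stressed replicate 1) and Gdpd3 at 1.85 (cypermethrin stressed replicate 2). Spata46 had 4.85 ± 6.35 CPM with vehicle alone and 1 count in all 4 libraries of both exposures.

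Of the 15 chosen genes 8 were fitted higher and 7 lower with both exposures, with 0.93 ± 0.75 for Hmox1, the haem oxygenase induced by oxidative stress, -0.30 ± 0.26 for the sodium channel gene Scn3a and 0.23 ± 0.21 for Sox6. Hmox1 had the opposite sign with limma voom (-0.25). Of 11 sodium channel genes 9 were fitted lower (median -0.13), and of 39 cell cycle genes 25 were fitted higher (median 0.22). By edgeR 0 of 13224 genes passed (smallest adjusted p = 1) and 197 had an unadjusted p under 0.05 (104 higher, 93 lower). Uniform p values would give 661, while splits of the libraries of these groups, the real one included, gave 170 to 488. DESeq2 and limma voom called 0 with 289 and 600 at an unadjusted p under 0.05. Fitted to only the groups compared, edgeR called 0 with 496, beside 454 for cypermethrin alone and 538 for stress alone in such fits. The low count of 197 thus depended on the fit and does not show that both exposures moved fewer genes. With the library code as a term edgeR called 0, and without cypermethrin stressed replicate 1 the count at an unadjusted p under 0.05 was 110. Within the library codes (2 against 2 libraries each) it called 13 in the first and 0 in the second (11 at an unadjusted p under 0.05). Adjusted over the list alone, 0 genes of any list passed. None of the 29 lists was called by camera (smallest adjusted p = 0.432), but leaving out cypermethrin stressed replicate 3 gave 1 call and leaving out vehicle non-stressed replicate 4 gave 3.

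The interaction asked whether the effect of cypermethrin differed between stressed and non-stressed dams. No gene passed. Cnih3, an auxiliary subunit of AMPA receptors, had a log2 interaction of -2.07 ± 0.51 (SE, n = 4 per group): its level was 79.0 ± 26.1 CPM with vehicle and 119 ± 68.7 with cypermethrin in the absence of stress, and 130 ± 60.7 and 46.6 ± 6.63 CPM under stress (SD). Sema5b, a guidance semaphorin, ran the other way (2.91 ± 0.81), with 39.5 ± 21.9 and 15.6 ± 6.99 CPM without stress and 13.8 ± 9.49 and 41.4 ± 15.0 CPM with it. Ripk4, a protein kinase gene, had no count in the 4 libraries of cypermethrin without stress, 3.36 ± 1.57 CPM with vehicle alone, 2.36 ± 3.83 with stress alone and 8.80 ± 9.07 with both, and the non-coding Snhg10 had no count in the 4 libraries of stress alone and 3.67 ± 1.17, 1.42 ± 2.02 and 3.91 ± 1.92 CPM with vehicle, cypermethrin and both. Dck (deoxycytidine kinase, -2.33 ± 0.62, and -1.60 without the library labelled vehicle stressed replicate 1), Gzf1 (-2.52 ± 0.68), Dbf4 (the activator of the replication kinase Cdc7, -2.87 ± 0.80), Rcor1 (a CoREST corepressor, -2.62 ± 0.75), Fam118b (-1.84 ± 0.54) and Chst15 (a sulfotransferase, -1.83 ± 0.55) had negative interactions. Without cypermethrin non-stressed replicate 3 those of Gzf1 and Rcor1 were -1.58 and -1.71.

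Of the 15 chosen genes 7 had positive and 8 negative interactions, with -0.74 ± 0.37 for Scn3a, -1.03 ± 0.51 for Cxcr4 and -0.93 ± 0.51 for Gad1. Without the 4 libraries that stood apart Scn3a turned to 0.22 and Gad1 to 0.04, and with limma voom Gad1 turned to 0.26. By edgeR 0 of 13224 genes passed (smallest adjusted p = 0.985) and 622 had an unadjusted p under 0.05 (213 higher, 409 lower), and DESeq2 and limma voom called 0 with 819 and 640 at an unadjusted p under 0.05. With the library code as a term edgeR called 0, and within the codes it called 9 in the first and 0 in the second (389 at an unadjusted p under 0.05). Adjusted over the list alone 1 gene passed, Nes among radial glia markers, with -0.91 ± 0.28 by edgeR (adjusted p = 0.0476). None of the 29 lists was called by camera (smallest adjusted p = 0.488, for glutamatergic neuron markers with a median of -0.27), but leaving out cypermethrin non-stressed replicate 3 gave 2 calls and leaving out replicate 4 of that group gave 1.

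Averaged over stress, 8 cypermethrin libraries were compared with 8 vehicle libraries. No gene passed by edgeR, and pericyte and meningeal fibroblast markers were higher with cypermethrin by camera with its preset correlation. Of their 17 tested members 16 were fitted higher, with a median log2 difference of 0.33 and a mean of 0.47 (camera adjusted p = 0.000586, and adjusted p = 0.930 with an estimated correlation). The extracellular matrix genes Lum (0.78 ± 0.28, SE), Vtn (0.90 ± 0.37) and Col3a1 (0.44 ± 0.19) and the smooth muscle actin gene Acta2 (2.63 ± 0.93, and 1.99 without cypermethrin non-stressed replicate 4) had the smallest p of the list, and none passed alone. The mean score of the list per library was 0.233 ± 0.390 with cypermethrin and -0.233 ± 0.589 with vehicle (SD, n = 8), a difference of 0.465 (exact two-sided permutation p = 0.0838). Within library codes the difference was 0.563 (3 against 4 libraries, exact permutation p = 0.257) and 0.262 (5 against 4, exact permutation p = 0.341), and camera did not call the list within either code (adjusted p = 0.437 and 0.165). Without the library labelled vehicle stressed replicate 1 it was 0.323 (exact permutation p = 0.165), and without cypermethrin non-stressed replicate 3 the camera call was lost (adjusted p = 0.104, 0 lists called). The number of lists called was 2 without cypermethrin stressed replicate 3 and 5 without cypermethrin non-stressed replicate 4, against 1 of 29 with all libraries.

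**Figure D4:**
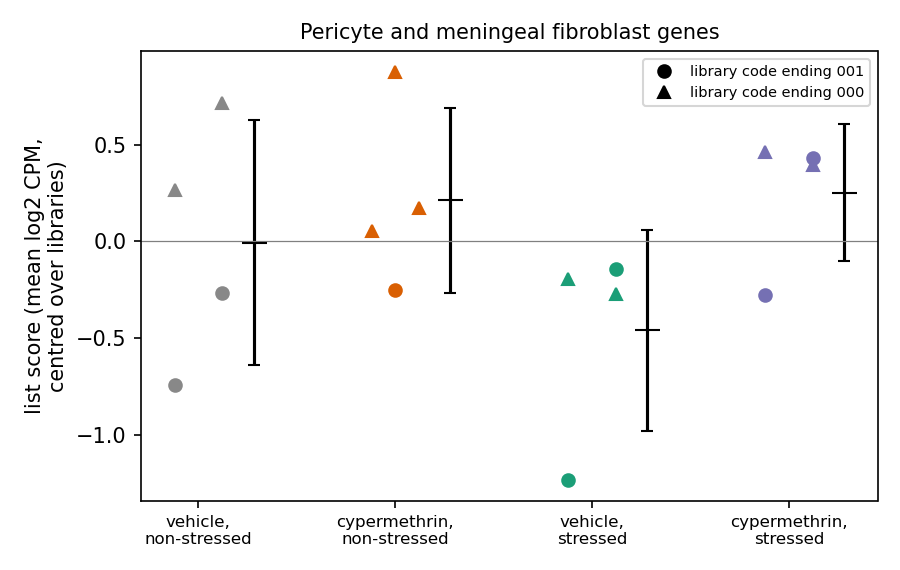
Mean centred log2 CPM of the pericyte and meningeal fibroblast markers (vertical axis) per library, by group; circles and triangles are the library codes, and black marks are the group mean ± SD. Group means are -0.00595 ± 0.635 for vehicle, 0.213 ± 0.477 for cypermethrin, -0.459 ± 0.519 for stress and 0.252 ± 0.355 for both, with the lowest value in the library labelled vehicle stressed replicate 1.

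The genes with the smallest p for cypermethrin averaged over stress were led by Cpeb1, with a log2 difference of 3.83 ± 0.78 (SE) and levels of 1.29 ± 0.741 CPM with vehicle, 0.315 ± 0.296 with stress, 29.2 ± 34.4 with cypermethrin and 3.30 ± 2.25 with both (SD, n = 4). Dnajc1 was next with -1.10 ± 0.25, and Dnajc25, another J-domain protein gene, had 2.38 ± 0.57. Without cypermethrin non-stressed replicate 3 Dnajc25 was at 1.48. Smug1, a uracil-DNA glycosylase (-1.60 ± 0.45), Psat1, an enzyme of serine synthesis (-1.53 ± 0.44), and Usp31 (-0.68 ± 0.19) were fitted lower, and Mmrn1 (1.47 ± 0.40), Atxn10 (0.47 ± 0.13) and Fank1 (2.61 ± 0.74) higher. Of the 15 chosen genes 6 were fitted higher and 9 lower, with -0.46 ± 0.24 for Dlx1, 1.03 ± 0.53 for Hmox1 and 0.33 ± 0.18 for Gad2, which was at -0.0026 without the 4 libraries that stood apart. By edgeR 0 of 13224 genes passed (smallest adjusted p = 0.545) and 607 had an unadjusted p under 0.05 (312 higher, 295 lower). DESeq2 called 1 gene, Cpeb1, with a log2 difference of 3.92 (adjusted p = 0.00503) and 764 at an unadjusted p under 0.05, and limma voom called 0 with 697. With the library code as a term edgeR called 0, and without vehicle stressed replicate 3 it called 1, Dnajc1, with -1.26 (edgeR adjusted p = 0.00896). Within the library codes it called 14 genes in the first and 0 in the second (317 at an unadjusted p under 0.05). Adjusted over the list alone Cnr1 (0.37 ± 0.11, adjusted p = 0.0207) and Psat1 (adjusted p = 0.0454) were among the genes that passed in edgeR.

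Averaged over cypermethrin, 8 stressed libraries were compared with 8 non-stressed libraries. No gene changed past the threshold. Fitted lower with stress were Tbp, the TATA-binding protein gene (-1.34 ± 0.37, SE, and -0.68 without cypermethrin non-stressed replicate 3), Ica1 (-1.41 ± 0.39, and -0.74 without cypermethrin non-stressed replicate 4), Chst11, a chondroitin sulfotransferase gene (-1.49 ± 0.41), Snhg11 (-1.0 ± 0.28), Grem1, a BMP antagonist gene (-3.28 ± 0.94), and Egln3, an oxygen-sensing prolyl hydroxylase gene (-3.09 ± 0.91). Grem1 and Egln3 had 80.5 and 52.6 CPM in cypermethrin non-stressed replicate 3 and at most 15.8 CPM elsewhere. They were at -2.17 and -1.81 without that library. Spata46 had counts in all 8 non-stressed libraries and in 2 of the stressed ones. Fibcd1 (2.93 ± 0.76), Exosc5, an RNA exosome subunit gene (2.39 ± 0.69), and Gdpd3 (2.84 ± 0.82, and 1.82 without cypermethrin stressed replicate 2) were fitted higher.

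Of the 15 chosen genes 7 were fitted higher and 8 lower with stress, with 0.54 ± 0.38 for Dlx2, 0.30 ± 0.24 for Dlx1 and 0.17 ± 0.15 for Sox6. Among glucocorticoid response genes 9 were fitted higher and 14 lower (median -0.06), among immediate early genes 13 higher and 8 lower (median 0.07), and among migration and guidance genes 28 higher and 17 lower (median 0.01). By edgeR 0 of 13224 genes passed (smallest adjusted p = 0.960) and 679 had an unadjusted p under 0.05 (323 higher, 356 lower), and DESeq2 and limma voom called 0 with 817 and 705 at an unadjusted p under 0.05. With the library code as a term edgeR called 0, and within the codes it called 7 in the first and 0 in the second (404 at an unadjusted p under 0.05). No gene of any list passed when adjusted over the list alone. None of the 29 lists was called by camera (smallest adjusted p = 0.959), but without vehicle non-stressed replicate 1 it called 1, the pericyte and meningeal fibroblast markers, which were fitted lower (adjusted p = 0.0329, and adjusted p = 0.991 with an estimated correlation).

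The effect of each exposure was also compared between the levels of the other. Across 13224 genes the cypermethrin differences with and without stress had r = -0.012 and rho = -0.0094, where 100 permutations of the group labels gave r from -0.088 to 0.153 and 64 were at or above the real value. The stress differences with and without cypermethrin had r = 0.0013 and rho = -0.00035, where permutations gave -0.089 to 0.083 and 59 were at or above. These correlations run across genes, which are not independent replicates. Within the first and second library code r was 0.0368 and -0.0871 for cypermethrin and 0.0439 and -0.0347 for stress.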

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

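The test for mixed male and female tissue, the fit without the 4 libraries that stood apart and the use of an interval in the test of few captured molecules were chosen only after the result was seen.

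The library labelled vehicle stressed replicate 1 stood apart in its group for the Y-linked genes Ddx3y, Eif2s3y and Kdm5d, with a gap to the nearest library of 0.964, 0.923 and 0.879 of the group's range on the log2 CPM scale, and it alone had high Xist. Dropout of Y-linked genes was argued against, since 0 of 1562 genes of the same level (50.98 to 84.6 CPM) were at 0 in that library, so that share to the power of 4 was 0. Male tissue mixed with female tissue was argued against as well, because the single Y-linked count allowed at most 0.879% of the median Y-linked level of the other libraries (exact 95% interval, counting error only). A female embryo recorded as male may account for it: the genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x, which escape X inactivation, had a median log2 ratio of 0.523 over the other libraries, whose own SD was 0.221, but Ddx3x alone was at -0.27 and the highest other library reached 0.526. No biological explanation was tested, and a sample exchanged with one from outside the series stays open.

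Pericyte and meningeal fibroblast markers were higher with cypermethrin averaged over stress by camera with a preset correlation (adjusted p = 0.000586), a call lost with an estimated correlation (adjusted p = 0.930). More meningeal or vascular tissue in the captured material, where genes of such tissue had counts, is a candidate explanation. A second list of 29 meningeal and pericyte genes shared 0 with the first. Its median log2 difference was 0.27 (camera p = 0.0158, and p = 0.344 with an estimated correlation). Both lists were read in the same libraries, however. Whether the libraries that stand apart produced it stays open, since without them the median was 0.22 against 0.33 and the adjusted p was 0.294, while camera called another list in that fit, Cajal-Retzius markers, which were lower (median -0.43, adjusted p = 0.00827, and adjusted p = 0.574 with an estimated correlation). Chance was not excluded either, because 10 of 100 splits of the libraries, the real one included, gave a camera p as small as the real 2.02e-05, the smallest other being 8.68e-11. An effect of cypermethrin on these cells stays among the open explanations, untested.

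The number of genes with counts ran from 12153 in the library labelled vehicle stressed replicate 1 to 16536 in cypermethrin stressed replicate 3. Sequencing depth as the whole cause was argued against, because at 2291283 counts in every library the range was still 26.6% of the median. Few captured molecules were tested as a cause in the library with the fewest genes. There 3 of 3284 genes with 50 to 200 CPM elsewhere were at 0, or 0.0914% (exact 95% interval 0.0188 to 0.267%). The whole interval lies below the 1% set beforehand as a sign of such loss, so the test gave this explanation no support. The value itself also lies under the bound of 0.1% set beforehand, which argues against such loss. The interval, added afterwards, spans that lower bound and the test rests on 1 library, so the explanation was not excluded. No biological explanation was tested.

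Each of the following values is the gap between the outermost library of a group of 4 and its nearest neighbour, as a share of the group's range. Chance flags about 1 in 20 groups, and such libraries were found in 17 of 284 groups for named genes (14.2 by chance), 8 of 116 for list scores (5.8 by chance), 4 of 20 for sex-linked genes (1 by chance) and 1 of 28 for library measures (1.4 by chance). Total counts were low in vehicle non-stressed replicate 1 (0.919). Cypermethrin stressed replicate 1 was low for the scores of migration and guidance genes (0.863), sodium channels (0.851), xenobiotic metabolism (0.869) and pericyte and meningeal fibroblast markers (0.908), and for Fkbp5 (0.933). The library labelled vehicle stressed replicate 1 was low for heat shock chaperones (0.899) and pericyte and meningeal fibroblast markers (0.881) and high for Dck (0.966). Vehicle non-stressed replicate 1 was low for heat shock chaperones (0.853), Bzw1 (0.844) and Ripk4 (0.921) and high for Nop16 (0.897) and Smug1 (0.868). Cypermethrin non-stressed replicate 4 was low for nuclear oxidative phosphorylation genes (0.84) and Sez6l (0.971) and high for Ica1 (0.871), and replicate 3 of that group was high for Mmrn1 (0.845) and Tbp (0.843). Cypermethrin stressed replicate 2 was low for Ddx3y (0.853) and Ociad2 (0.935). Vehicle non-stressed replicate 2 was high for Cxcr4 (0.864) and Egln3 (0.835). Dnajc1 was low in vehicle stressed replicate 3 (0.841), and Lhx6 was high in vehicle stressed replicate 4 (0.893). Spata46 was high in vehicle stressed replicate 4 (1) and in cypermethrin stressed replicate 3 (1). The others of each group had no count, which fixes the value at 1, and cypermethrin stressed replicate 3 had only 1 count.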

How the results depend on the processing

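The fits without the 4 libraries that stood apart and within each library code were chosen only after the data were seen. In 5 of the 6 comparisons edgeR, DESeq2 and limma voom called 0 genes under each alternative run on libraries of both codes, with 110 to 1268 at an unadjusted p under 0.05, and for cypermethrin averaged over stress DESeq2 called 1 gene and leaving out single libraries gave 0 to 1 (1 without vehicle stressed replicate 3). Of 1737 recomputed fold changes of named genes 1731 kept their sign and 6 reversed. Most of these genes were picked for a small p in the same libraries, which the refits mostly shared. Their kept signs were thus largely fixed in advance and are no evidence of a change. All 6 reversals concerned genes chosen beforehand. With limma voom Gad1 was at -0.12 for stress alone and 0.26 for the interaction, and Hmox1 at -0.25 for both exposures. Without the 4 libraries Scn3a was at 0.22 and Gad1 at 0.0446 for the interaction, and Gad2 at -0.0026 for cypermethrin averaged over stress. For that average camera with an estimated correlation and fry called 0 lists each, with adjusted p of 0.930 and 0.888 for the pericyte and meningeal fibroblast markers, where both tests allow the genes of a list to vary together. Those markers had an adjusted p of 0.294 without the 4 libraries and from 5.44e-06 (without vehicle non-stressed replicate 4) to 0.104 (without cypermethrin non-stressed replicate 3) with single libraries left out. Without the 4 libraries camera called 1 list for cypermethrin alone, Cajal-Retzius markers (lower), and 1 for the interaction, pericyte and meningeal fibroblast markers (positive). For stress averaged over cypermethrin it called 3, all higher: medial ganglionic eminence lineage genes (median 0.22), immediate early genes (0.25) and Cajal-Retzius markers (0.41). Their camera adjusted p was 0.0343 each, and 0.249, 0.249 and 0.481 with an estimated correlation. For cypermethrin averaged over stress it called 1, the Cajal-Retzius markers, which were lower (adjusted p = 0.00827, and 0.574 with an estimated correlation). With genes of a mean of 50 or more counts camera called 1 for both exposures, the cell cycle. With single libraries left out it called 0 to 2 lists for cypermethrin alone, 0 to 1 for stress alone, 0 to 3 for both, 0 to 2 for the interaction, 0 to 5 for cypermethrin averaged and 0 to 1 for stress averaged, the highest without cypermethrin non-stressed replicate 3 or 4, vehicle non-stressed replicate 1, vehicle non-stressed replicate 4, cypermethrin non-stressed replicate 3, cypermethrin non-stressed replicate 4 and vehicle non-stressed replicate 1, in that order. The correlation of the stress effects was 0.0431 without the 4 libraries and -0.0193 to 0.0386 with single libraries left out, and that of the cypermethrin effects -0.036 to 0.016. Within the first code edgeR called 2 genes for cypermethrin alone, 45 for stress alone, 13 for both, 9 for the interaction, 14 for cypermethrin averaged and 7 for stress averaged, and camera called 1 list for stress averaged and 0 for cypermethrin averaged. Within the second code edgeR called 0 in each, and camera called 1 list for cypermethrin alone, 1 for stress alone, 2 for the interaction, 1 for stress averaged and 0 for cypermethrin averaged. The pericyte and meningeal fibroblast markers had an adjusted p of 0.437 and 0.165 in the codes, and the correlations were 0.0368 and -0.0871 for cypermethrin and 0.0439 and -0.0347 for stress. Of 85 fold changes of named genes 27 moved over 1.5 times with 1 library left out. Except where stated the cause was not tested. Of the recomputed counts of called genes and called lists, mostly 0, 222 stayed within 1.5 times the value with all libraries and 33 did not, counts at an unadjusted p left aside. At 2291283 counts per library 12132 to 15907 genes had counts, against 12153 to 16536 at full depth, so most of the spread remained at equal depth. A pseudocount of 0.1 was not run because the table holds counts, and no paired analysis was possible because replicate numbers follow accession order only.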

Other observations

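The channel, receptor and enzyme genes described here were picked from lists fixed earlier only after their values were seen, and the fits within a library code were chosen after the data were seen.

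The sodium channels on which pyrethroids act had counts in the captured material at very different levels. Scn3a, a channel gene of embryonic brain, had the highest level of the listed sodium channel genes with 291.5 ± 98.0 CPM (SD, n = 16), followed by Scn8a with 174 ± 75.6, the auxiliary subunit gene Scn3b with 155 ± 42.7 and Scn2a with 129 ± 27.3 CPM. Scn1a, a main channel of mature fast-spiking interneurons, had 30.4 ± 11.2 CPM, and the auxiliary subunit gene Scn2b had 5.66 CPM. The intracellular channel partners Fgf13, Fgf12 and Fgf14 had 104, 68.4 and 34.8 CPM. The muscle channel gene Scn4a and the sensory neuron genes Scn10a and Scn11a were below 0.1 CPM. The calcium channel gene Cacna1e had 621 ± 138 CPM.

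Among receptors and transporters there were 94.1 ± 30.0 CPM of the chloride importer gene Slc12a2 and 26.2 ± 10.3 CPM of the exporter gene Slc12a5 (SD, n = 16), beside 849 ± 122 CPM of the glutamate receptor gene Gria2. The glucocorticoid receptor gene Nr3c1 had 25.3 ± 20.7 CPM and its target Fkbp5 35.3 ± 10.7 CPM. Immediate early genes were uneven, with 0.839 CPM of Fos and 0.248 of Arc against 37.5 ± 26.8 of Egr1 and 199 ± 66.4 of Nr4a3. Of the cytochrome P450 genes Cyp1b1 had 56.2 ± 30.1 CPM, and Cyp2b9, Cyp2c29 and Cyp2e1 had no count in any library.

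In each of the 6 comparisons 5% or more of the splits of the libraries, the real one included, gave as many genes at an unadjusted p under 0.05, so chance was not excluded for any of the 6 counts. For cypermethrin alone 30 of 35 splits gave at least the real 491 (highest other 809), for stress alone 12 of 35 gave at least 672 (highest other 953), and for both exposures 25 of 35 gave at least 197 (highest other 488). For the interaction 73 of 100 gave at least 622 (highest other 1019), for cypermethrin averaged over stress 63 of 100 gave at least 607 (highest other 948), and for stress averaged over cypermethrin 31 of 100 gave at least 679 (highest other 1041).

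Within the first library code, with 7 libraries in groups of 1 or 2, splits of the libraries by chance were counted in the same way for genes called by edgeR, 100 of 315 each and the real one included. Chance was not excluded for cypermethrin alone (35 splits with at least the real 2, highest other 654), the interaction (19 with at least 9, highest other 291), cypermethrin averaged over stress (11 with at least 14, highest other 217) and stress averaged over cypermethrin (14 with at least 7, highest other 291). Under 5% of the splits gave as many for stress alone (2 with at least 45, highest other 57) and both exposures (1 with at least 13, highest other 8). With no adjustment for the 6 counts, in a fit chosen after the data were seen, this does not exclude chance. For stress alone 38 of the 45 genes were highest in the library labelled vehicle stressed replicate 1, and without it edgeR called 6 for stress alone and 30 for both. Counts several times the real one came only in the 4 comparisons that include the group of 1 library. The splits behind them placed the library labelled vehicle stressed replicate 1 alone in that group. For both averages no split of another kind reached the real count. Why these splits gave so many calls was not tested. In the second code edgeR called 0 genes in each comparison.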
